A study of Homo sapiens with 18 samples.

How the data were processed

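ChIP-seq libraries of MDA-MB-231 cells were grouped by the antibody and cell stock in their titles: 18 libraries in 9 groups of 2. Nothing in the labels says whether the libraries of a group came from separate cultures. Each deposited list is 1 per target and does not resolve the libraries, so the p-values here compare genes or peaks within lists and cover no variation between libraries. Chromatin was prepared by enzymatic digestion, per the labels' protocols. Per the submitters' processing notes, the tools were Trim Galore (version not given in the sources used here), Bowtie2 2.4.5, SAMtools 1.6 and MACS2 2.2.7.1, with genome build hg38. Which control each list was called against, and whether the libraries were pooled first, is not given in the sources used here. All lists are in narrow-peak form, including those of the broad marks H3K27me3 and H2AK119ub. Enzymatic digestion and a narrow-peak caller can split a broad domain into many peaks.

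The deposited peak lists give a score, which equals the whole part of 10 times the −log10 q in 99.8% to 100% of peaks. The fold is the authors' ratio of signal over background at the summit. The deposited −log10 p-value and −log10 q-value are those of the authors' peak caller, and the highest q-value in any list was between 0.0498 and 0.0500. The position of the summit is given in bp from the start of the deposited peak. Folds, scores and q-values were used only to describe, rank or filter peaks within a list. The lists hold no read counts, so depth per library is unknown and no interval covers it.

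Gene positions came from the RefSeq annotation of assembly GRCh38.p14, which matches the build of the lists. The 19974 protein-coding genes on chromosomes 1 to 22 and X were the units. The design, fixed before the data were examined, named promoters around transcription start sites. The reference used here gives gene records without strand, so a window of 1 kb either side of both ends of each record was used instead, and a gene counted as having a target when at least 1 bp of a peak fell in either window. Records reach the outermost transcript, so a promoter used inside a record, as at ASNS, MTRR or FDFT1, can be missed. Sequence was not used here, which left out the planned strata of CpG content and the planned count of E-box motifs at MYC summits. Fisher's exact test, which the design named for that case, was used among genes with H3K4me3, and random lists were matched on H3K4me3 in place of CpG content.

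Shares of peaks near gene ends or overlapping another list were compared with circular shifts along each chromosome, 200 for KDM2B and 20 for the other lists, with one-sided permutation p-values. Overlap meant at least 1 bp. Intervals of shares are 95% Wilson intervals and cover counting error only. Shares of genes were compared with Fisher's exact test, two-sided, with p-values held at 1e-300 or above, and odds ratios have 95% Woolf intervals, with 0.5 added to each cell where one was 0. Benjamini-Hochberg adjustment was applied over 13 odds ratios and separately over 108 tests of lists by targets, with a threshold of 0.05. Genes at neighbouring positions share windows and peaks and are not independent, which makes these p-values too small. Common odds ratios over 10 by 10 strata of H3K4me3 width and fold are Mantel-Haenszel estimates.

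The 18 gene lists, fixed beforehand from general knowledge, were enzymes of serine, glycine and one-carbon metabolism; of glutamine, glutamate, aspartate, proline and arginine; of methionine, cysteine and glutathione; and of catabolism of other amino acids. They also held amino acid transporters, cytosolic aminoacyl-tRNA synthetases, ATF4-responsive stress genes, ribosome biogenesis and nucleotide synthesis genes, ncPRC1.1 subunits, other Polycomb subunits, developmental transcription factors, luminal and epithelial genes, mesenchymal and basal genes, haematopoietic genes, enzymes of glycolysis, cholesterol synthesis and the tricarboxylic acid cycle, and olfactory receptors. All members matched a gene record. For each list the share of genes was also placed among 10000 random lists of the same size and the same number of genes with H3K4me3.

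Named genes followed a rule fixed beforehand: 13 core genes in every list; of each gene list, up to 4 members with the highest fold at a peak of the target discussed; over all genes, the 10 with the highest KDM2B fold and the 5 with the highest fold of each other target; and all members of any count of 5 or fewer. Names given outside that rule, such as genes that lack a peak, were chosen after their values were seen.

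Alternatives were windows of 500 and 2500 bp, peaks with q under 1e-5, the 15000 peaks of highest fold per list, summits in place of whole peaks, at least 50% of a KDM2B peak inside a window, 1 gene per set of overlapping windows, chromosome X left out, broad marks merged across 3 kb, merged domains of at least 2 kb, and genes with H3K4me3 as the background. Whole genes with 1 kb around them, only the gene end with H3K4me3, and strata of H3K4me3 over genes or over peaks were added after the data were seen. Leaving out 1 library at a time could not be done with lists that do not resolve them. The functions were tested on simulated data: of 200 lists of 30 genes out of 19974 with a planted odds ratio of 4 for KDM2B, 93.5% were recovered, of 200 lists of 130 genes 100%, and 2.5% of lists without an effect were called. Overlap counts were checked against bedtools 2.31.1. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3. ATF4 and input libraries, and peaks outside chromosomes 1 to 22 and X, were left out of the comparisons. Folds at a few members of the gene lists are not reported here.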

Results

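The data were peak lists from chromatin immunoprecipitation sequencing (ChIP-seq) of MDA-MB-231, an established line of triple-negative breast cancer cells. KDM2B, a histone demethylase that binds unmethylated CpG DNA and belongs to the Polycomb complex ncPRC1.1, was profiled in the parental line beside the transcription factors MYC and ATF4. Trimethylated H3K4, found at active promoters, and trimethylated H3K27 and ubiquitinated H2AK119, the marks written by the Polycomb complexes PRC2 and PRC1, were profiled in the same cells. Acetylated H3K27, a mark of active promoters and enhancers, was profiled in cells that carried an empty vector. The 18 libraries formed 9 groups of 2, input libraries of both cell stocks included. One peak list per target was analysed for 6 targets, so no value has a replicate error, and the ATF4 libraries were not analysed here. The lists held 20018 KDM2B peaks, 49833 MYC peaks, 71597 H3K4me3 peaks, 95771 H3K27ac peaks, 234493 H2AK119ub peaks and 306484 H3K27me3 peaks. Read depth is unknown, since the lists give no counts. Lengths of lists were therefore not compared as amounts of binding. Fold enrichment at a peak is the authors' value throughout and ranks peaks only within its own list.

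KDM2B was enriched at the ends of genes. Of its 19982 peaks on chromosomes 1 to 22 and X, 51.0% overlapped a window of 1 kb either side of an end of a protein-coding gene, against 3.70% on average after the peaks were shifted along their chromosomes. The ratio was 13.8, and the one-sided permutation p of 0.00498 was the smallest that 200 shifts can give. The share was 45.0% with windows of 500 bp, 47.7% with the summit inside a window, 47.9% with at least 50% of the peak inside and 61.5% with the 15000 peaks of highest fold. The same ratio was 6.70 for MYC, 3.93 for H3K4me3, 3.75 for H3K27ac, 1.92 for H2AK119ub and 0.954 for H3K27me3. Peaks inside genes and away from their ends made up 18.0% of the KDM2B list, and peaks outside genes 31%. KDM2B peaks covered 11 Mb with a median width of 385 bp, while H3K27me3 peaks covered 359 Mb. The highest KDM2B fold at a gene end was 15.2 at FBRS, which encodes a protein related to AUTS2, a subunit of other PRC1 complexes. EFEMP1, a gene of extracellular matrix, followed at 10.6, and IRF2BPL at 10.5. The peak shared by CAMTA2 and SPAG7 had a fold of 10.2, ABHD6 one of 10.0, the peak of FAM43A and LOC124909474 one of 9.93, EPB41L4A one of 9.83 and SNX15 one of 9.67.

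Most KDM2B peaks lay on MYC peaks and on marks of active promoters. MYC peaks were overlapped by 81.7% of KDM2B peaks (95% Wilson interval 81.1 to 82.2), H3K4me3 peaks by 78.3% (77.7 to 78.9) and H3K27ac peaks by 74.1% (73.5 to 74.7). After shifting, these shares were 3.04%, 6.90% and 6.78%. H2AK119ub was overlapped by 24.6% of KDM2B peaks against 11.7% after shifting, and H3K27me3 by 4.91% against 18.1%. MYC, H3K4me3 and H3K27ac were all present at 72.4% of KDM2B peaks. In the other direction, 26.4% of MYC peaks overlapped a KDM2B peak. The KDM2B peaks without H3K4me3 numbered 4333, and 1.27% of them were near a gene end. A further count, of KDM2B peaks that overlapped none of the other 5 lists, came to 2722, or 13.6%. The one-sided permutation p was 0.00498 for MYC, H3K4me3, H3K27ac and H2AK119ub, the smallest possible, and 1 for H3K27me3.

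**Figure D1:**
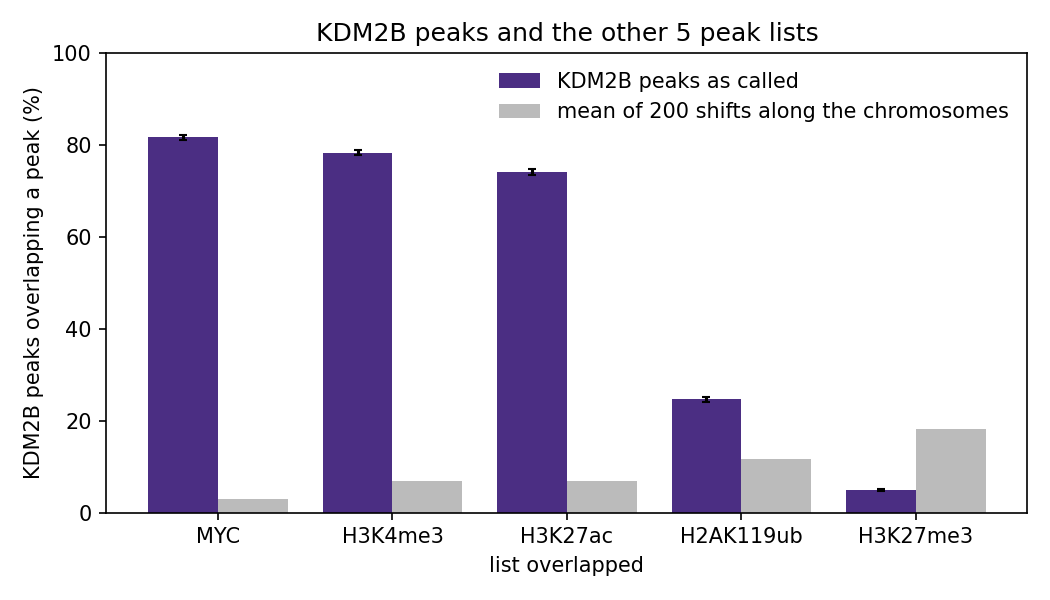
Share of KDM2B peaks (%, vertical axis) that overlapped a peak of each of the other 5 lists (horizontal axis), as called (dark bars, with 95% Wilson intervals) and as the mean of 200 shifts along the chromosomes (grey bars). MYC was overlapped by 81.7% of KDM2B peaks against 3.04% after shifting, and H3K27me3 by 4.91% against 18.1%.

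Counted over genes, the question was whether genes with KDM2B carried the other factors and marks more often than genes without it. Of 19974 protein-coding genes, 9321 had KDM2B at an end (46.7%, 95% Wilson interval 46.0 to 47.4), 12817 had MYC (64.2%) and 13863 had H3K4me3 (69.4%). H3K4me3 was at 99.5% of genes with KDM2B and at 43.1% of the others, an odds ratio of 267 (95% interval 199 to 357). H3K27ac was at 96.1% and 35.4% (odds ratio 45.1, 40.3 to 50.5), and MYC at 99.3% and 33.4% (288, 225 to 370). Fisher's exact test, two-sided, gave p at or below 1e-300 for each of the 3, the smallest value printed here. Only 64 genes had KDM2B without MYC, and 33 of these had H3K4me3. The commonest combination was KDM2B, MYC, H3K4me3 and H3K27ac without Polycomb marks, at 5245 genes (26.3%). The same 4 with H2AK119ub were at 3094 genes (15.5%), and MYC, H3K4me3 and H3K27ac without KDM2B at 2099 (10.5%). No list had a peak at either end of 1961 genes (9.82%). Over all alternative settings the odds ratio of H3K4me3 ranged from 17.3 to 491, of H3K27ac from 8.60 to 47.4 and of MYC from 38.4 to 314. Because nearly all genes with KDM2B had H3K4me3, the comparison was repeated among genes with H3K4me3.

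Among the 13863 genes with H3K4me3, MYC was at 99.6% of those with KDM2B and 73.8% of those without, an odds ratio of 99.4 (95% interval 70.2 to 141; Fisher's exact test, two-sided, p at or below 1e-300). MYC and H3K4me3 without KDM2B were found at 3386 genes. KDM2B was most frequent where H3K4me3 was strongest. With the H3K4me3 peaks ranked by fold in 10 classes of equal size, 88.8% of the highest class overlapped KDM2B, against 0.755% of the lowest. The median width of these classes was 6485.5 bp and 300 bp, and wider peaks can overlap more by their length alone. MYC overlapped 99.97% and 10.3% of the same classes, and H3K27ac 99.9% and 24.1%. When genes were matched on the width and fold of their H3K4me3 peaks, a setting added after the data were seen, the odds ratio of MYC was 21.1 (15.1 to 29.3). Without matching it was 7.11 with the 15000 peaks of highest fold per list, H3K4me3 included (92.4% against 63.2%), and 113 with chromosome X left out. With only the KDM2B and MYC lists cut to 15000 peaks, over the 13863 genes and with the matching, it was 3.58.

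**Figure D2:**
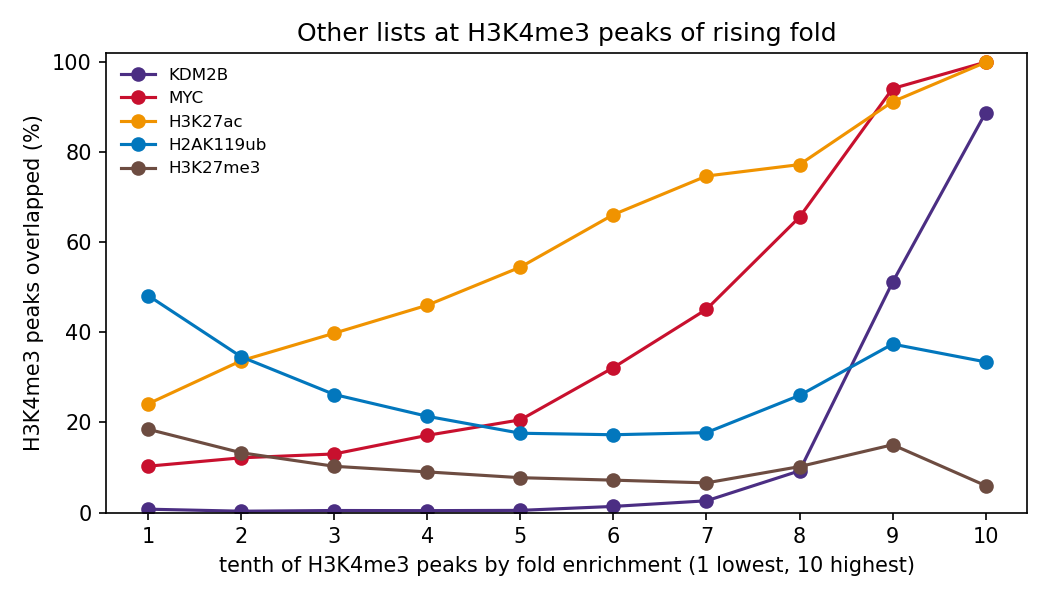
Share of H3K4me3 peaks (%, vertical axis) that overlapped a peak of KDM2B, MYC, H3K27ac, H2AK119ub or H3K27me3 (coloured lines), by class of the H3K4me3 peaks, 10 of equal size from the lowest to the highest authors' fold (horizontal axis). KDM2B went from 0.755% to 88.8% and MYC from 10.3% to 99.97%, while H2AK119ub was 48.2% in the lowest class and 33.4% in the highest.

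With windows of 1 kb, both Polycomb marks were less frequent at genes with KDM2B than at the others, and for H2AK119ub this depended on the window. H3K27me3 was at 9.17% of genes with KDM2B and 42.4% of the others (odds ratio 0.137, 0.127 to 0.149; Fisher's exact test, two-sided, p at or below 1e-300). H2AK119ub was at 41.9% and 48.0% (odds ratio 0.783, 0.740 to 0.828; exact p = 1.06e-17, adjusted p = 1.72e-17, two-sided). The latter odds ratio was 0.973 with windows of 2500 bp (exact p = 0.350) and 1.09 over whole genes (exact p = 0.00241), a setting added after the data were seen. These shares count a gene when a mark is at either end, even opposite KDM2B. At the end with H3K4me3 alone, in genes with it at 1 end, another added setting, H2AK119ub was at 21.2% with KDM2B and 26.4% without (odds ratio 0.748), and H3K27me3 at 4.74% and 15.3% (0.276). Both marks together were at 4315 genes, H2AK119ub without H3K27me3 at 4700 and H3K27me3 without H2AK119ub at 1054. H3K27me3 was at 47.9% of genes with H2AK119ub and 9.62% of those without (odds ratio 8.63, 8.0 to 9.31; exact p at or below 1e-300, two-sided). Of the 9321 genes with KDM2B, 3176 had H2AK119ub without H3K27me3 and 730 had both. Among genes with H3K4me3, H2AK119ub was at 41.7% of those with KDM2B and 42.7% of those without (odds ratio 0.960, 0.894 to 1.03; exact p = 0.265, adjusted p = 0.287, two-sided), a difference that did not pass the test. H3K27me3 was at 8.98% and 23.5% of them (odds ratio 0.322, 0.291 to 0.355; exact p = 3.82e-113, two-sided). The direction for H2AK119ub turned with the setting: the odds ratio was 0.848 with chromosome X left out, 0.854 with windows of 500 bp and 0.870 with summits. It was 1.15 with windows of 2500 bp, 1.39 with the 15000 peaks of highest fold per list and 1.65 after matching genes on H3K4me3. H3K27me3 moved to 1.08 after that matching and to 2.75 with H3K4me3 peaks as the units. With the KDM2B peaks themselves in 10 such classes by fold, H2AK119ub was at 40.5% of the highest class, 17.5% of the seventh and 29.2% of the lowest.

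The study's title names amino acid metabolism, so 13 genes chosen beforehand were examined in every list. MYC and H3K4me3 were at an end of all 13, and KDM2B at 11. Serine is made by PHGDH, PSAT1 and PSPH in turn, and the KDM2B fold was 2.42 at PHGDH, 4.28 at PSAT1 and 7.65 at PSPH, the last in a peak shared with CCT6A. In mitochondrial one-carbon metabolism it was 2.49 at SHMT2 and 3.10 at MTHFD2. The KDM2B peaks at PHGDH and SHMT2 were near the q limit of the list, with −log10 q of 1.92 and 1.84. That at the end of ASNS had 4.78. These peaks fell short of the setting with q under 1e-5. SLC7A5 and SLC3A2, which form a carrier of large neutral amino acids, had KDM2B folds of 4.11 and 3.59, and the glutamine carrier SLC1A5 had 3.54. MYC had 6.92 and ATF4 3.41. KDM2B had no peak at the ends of SLC7A11, the cystine carrier, nor anywhere inside it. Its own gene had no KDM2B peak at an end but 5 inside, with a highest fold of 7.52. The MYC fold was 36.3 at both ATF4 and PSAT1, 31.1 at SLC3A2, 24.3 at SLC7A5, 24.0 at SLC1A5, 23.6 at PSPH, 22.1 at SHMT2, 13.4 at MTHFD2 and 10.6 at SLC7A11. It was 7.47 at KDM2B, 6.55 at MYC itself, 5.21 at PHGDH and 4.23 at ASNS. Inside the records the MYC fold reached 17.0 at KDM2B and 18.6 at ASNS.

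Some of these genes carried Polycomb marks as well as MYC, in part at the opposite end. PHGDH (chromosome 1, 119711934 to 119744215 in hg38) had KDM2B at 119712175 to 119712440 and MYC at 119711955 to 119713681. H3K27me3 peaks covered 29128 bp of the gene and the 1 kb around it, with a highest fold of 4.52, and 22 H2AK119ub peaks covered 13047 bp. ASNS, which makes asparagine (chromosome 7, 97851677 to 97928441), had KDM2B of fold 2.86, H2AK119ub of 3.42 and H3K27me3 of 4.34 at the upper end of its record. A second site inside the record held KDM2B of fold 3.83 at 97871935 to 97872396, with MYC of 18.6, H3K4me3 of 45.2 and H3K27ac of 15.6. That site had no H2AK119ub or H3K27me3 peak, while the upper end had H3K4me3 of 13.6 and no H3K27ac. SLC7A5 (chromosome 16, 87830023 to 87869507) had 26 H2AK119ub peaks over 27697 bp, 6 KDM2B peaks and no H3K27me3. SLC7A11 (chromosome 4, 138164097 to 138242349) had no H2AK119ub or H3K27me3. H2AK119ub was at an end of 5 of the 13 genes, namely ASNS, PHGDH, SHMT2, SLC1A5 and SLC7A5, and H3K27me3 at 3, namely ASNS, PHGDH and MTHFD2. H2AK119ub at PHGDH and SHMT2 and H3K27me3 at MTHFD2 were within 1 kb of the upper end of the record only, while KDM2B and MYC were at the lower end. Exons and introns were not resolved here.

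**Figure D3:**
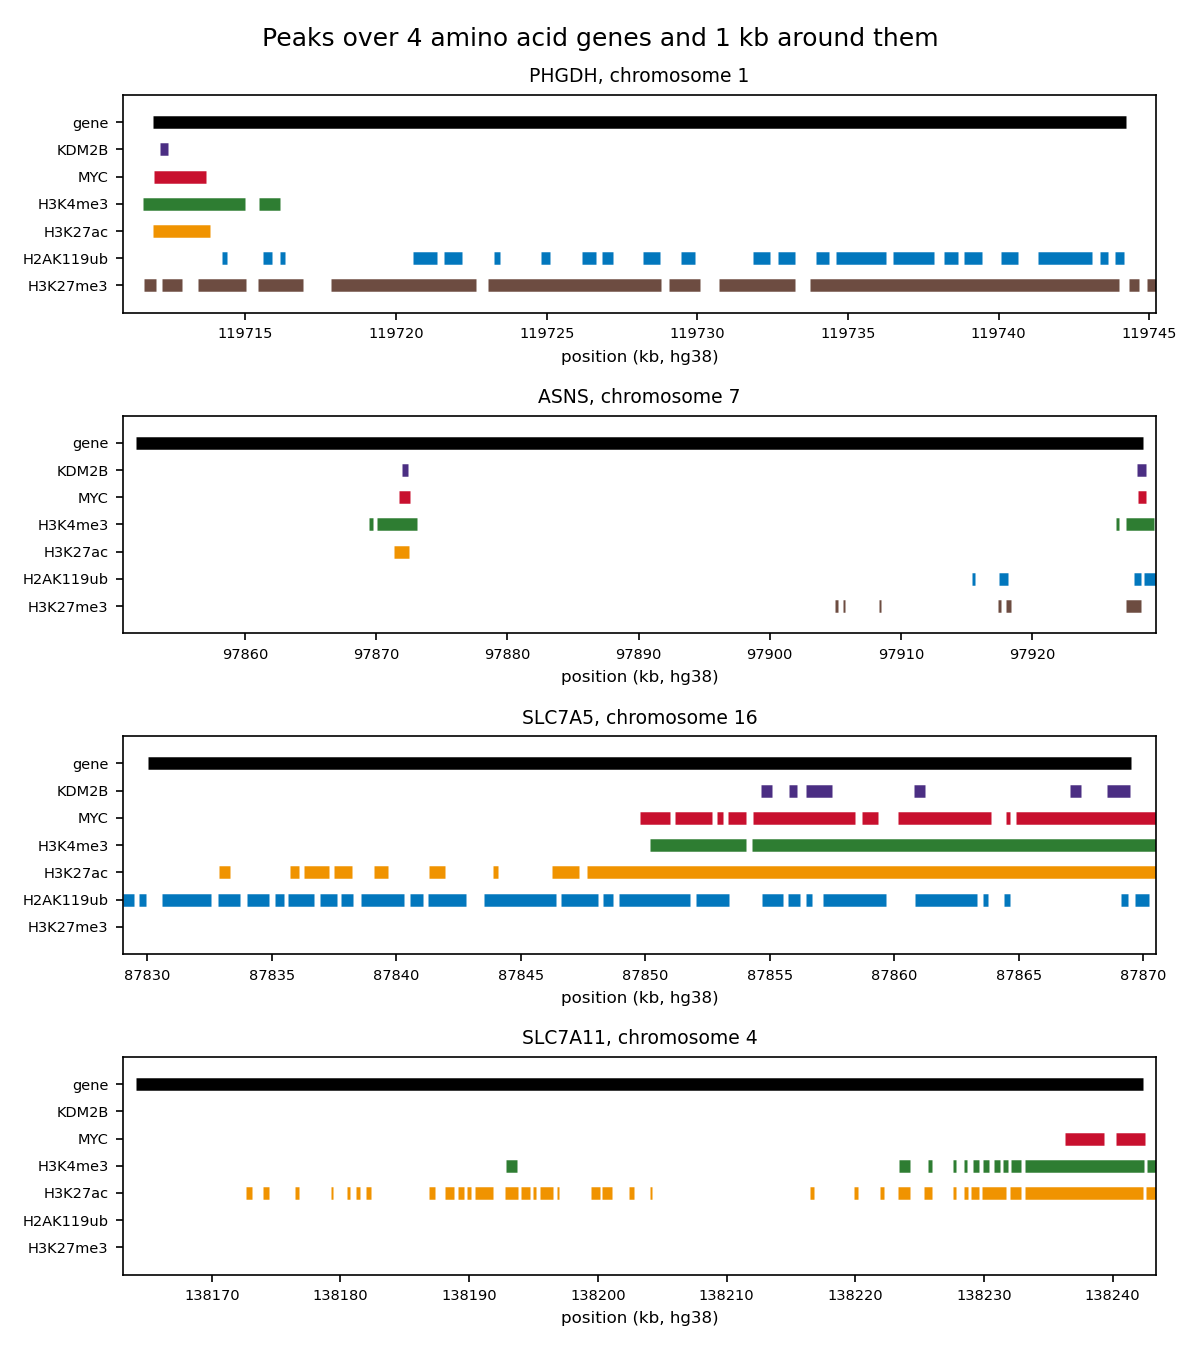
Peaks of the 6 lists (coloured bars, 1 line per list) over PHGDH, ASNS, SLC7A5 and SLC7A11 (black bars, the gene record) and 1 kb around each, with position in kb of hg38 on the horizontal axes. H3K27me3 covered 29128 bp at PHGDH, KDM2B lay at both an end of ASNS and a site inside it, SLC7A5 had 26 H2AK119ub peaks, and SLC7A11 had no KDM2B peak.

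Over the 173 amino acid genes together, KDM2B was at 93 (53.8%, against 46.6% of other genes) and MYC at 123 (71.1% against 64.1%). The odds ratios were 1.33 (0.987 to 1.80; Fisher's exact p = 0.0661, adjusted p = 0.0860) and 1.38 (0.990 to 1.92; exact p = 0.0564, adjusted p = 0.0814), two-sided, and neither passed the test. Both factors were at 92 genes (53.2% against 46.3%; odds ratio 1.32, 0.977 to 1.78; exact p = 0.0780, two-sided). H2AK119ub was at 75 (odds ratio 0.930, 0.687 to 1.26; exact p = 0.646, two-sided). Counting 1 gene for each set of overlapping windows gave 1.69 for KDM2B, 1.51 for MYC and 1.66 for both, each past an unadjusted 0.05. Against genes with H3K4me3 the KDM2B odds ratio was 1.096 (0.760 to 1.58; exact p = 0.647, two-sided, unadjusted). The MYC odds ratio was 1.002 (0.553 to 1.82) and did not pass either. At the end with H3K4me3 alone the odds ratios were 1.19 for KDM2B, 1.01 for MYC and 1.15 for both, and none passed.

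The 6 amino acid lists differed in their shares. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had KDM2B at 17 of 20 (85.0%; odds ratio 6.49, 1.90 to 22.1; Fisher's exact test, adjusted p = 0.00199). IARS1, MARS1 and QARS1 lacked it, while AARS1 had the highest fold at 4.90, then KARS1 at 4.66, CARS1 at 4.62 and GARS1 at 4.10. MYC, H3K4me3 and H3K27ac were at all 20 and H3K27me3 at 0. Enzymes of glutamine, glutamate, aspartate, proline and arginine had KDM2B at 21 of 31 (67.7%; odds ratio 2.4, 1.13 to 5.11; exact test, adjusted p = 0.0451). PRODH, which starts proline breakdown, had a fold of 6.25, ODC1, which makes putrescine, 6.01, the glutamine synthetase gene GLUL 5.94 and OAT 5.71. The other 4 lists did not pass the test for KDM2B. Serine, glycine and one-carbon enzymes had it at 14 of 23 (60.9%, adjusted p = 0.311 by the exact test), with TYMS at 5.26 and MTHFD1L at 5.11. Methionine, cysteine and glutathione enzymes had it at 9 of 19 (47.4%), with AHCYL1 at 4.98, GCLM at 4.87 and MAT2A at 4.52. Catabolic enzymes of branched-chain, aromatic and other amino acids had it at 17 of 39 (43.6%), with GSTZ1 at 5.65 and HPD at 5.03. Amino acid transporters had it at 15 of 41 (36.6%), with SLC43A1 at 7.15, SLC43A2 at 6.98, the taurine carrier SLC6A6 at 6.26 and SLC7A6 at 5.74. When the background was restricted to genes with H3K4me3, neither the synthetases (odds ratio 2.81, 0.822 to 9.58; exact test, adjusted p = 0.386) nor the glutamine list (2.60, 0.892 to 7.58; exact test, adjusted p = 0.375) passed.

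**Figure D4:**
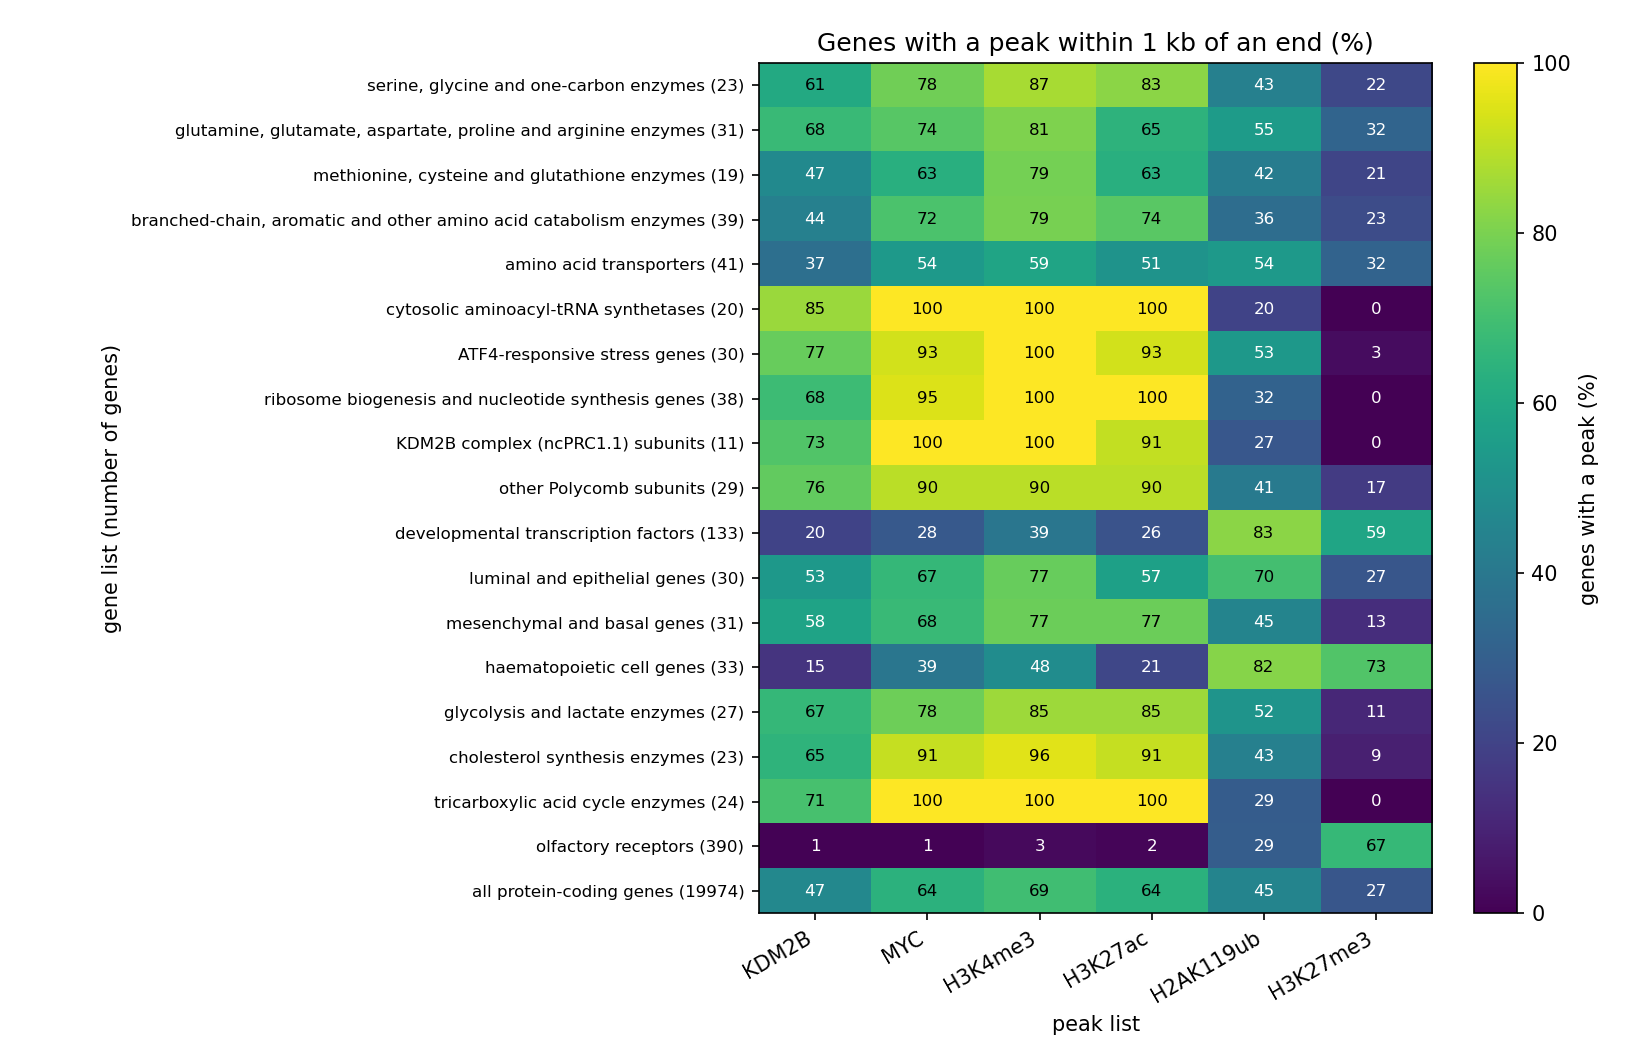
Share of genes (%, colour and number in each cell) with a peak within 1 kb of either end, for 18 gene lists and all protein-coding genes (vertical axis, number of genes in brackets) and the 6 peak lists (horizontal axis). KDM2B was at 85.0% of cytosolic aminoacyl-tRNA synthetases, 46.7% of all genes and 20.3% of developmental transcription factors.

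Genes known to respond to ATF4, the factor of the amino acid stress response, had KDM2B at 23 of 30 (76.7%; odds ratio 3.76, 1.61 to 8.77; Fisher's exact test, adjusted p = 0.00469) and MYC at 28. The autophagy receptor gene SQSTM1 had a KDM2B fold of 8.57 in a peak shared with MGAT4B, SESN2 had 7.21, PPP1R15A, which reverses eIF2 phosphorylation, 6.48 and PMAIP1 6.40. Ribosome biogenesis and nucleotide synthesis genes had KDM2B at 26 of 38 (68.4%; odds ratio 2.48; exact test, adjusted p = 0.0221) and MYC at 36 (odds ratio 10.1; exact test, adjusted p = 0.000131). The MYC fold reached 76.1 at PPAT, 73.0 at NOLC1, 72.5 at the nucleolin gene NCL and 68.8 at WDR43. Against genes with H3K4me3 the KDM2B odds ratios were 1.63 for the ATF4-responsive list (exact test, adjusted p = 0.663) and 1.07 for the ribosome list (exact test, adjusted p = 1), so neither passed. The MYC odds ratio of the ribosome list fell to 1.76 against the same genes (exact test, adjusted p = 0.911) and did not pass either.

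KDM2B was also counted at genes for Polycomb proteins. Among ncPRC1.1 subunits, 8 of 11 had KDM2B (72.7%; Fisher's exact test, adjusted p = 0.216), with RNF2 at a fold of 5.58, USP7 at 4.73, PCGF1 at 4.48 and SKP1 at 4.10. KDM2B, RYBP and YAF2 lacked it. Other Polycomb subunits had it at 22 of 29 (75.9%; odds ratio 3.60, 1.54 to 8.43; exact test, adjusted p = 0.00718), with PHC2 at 6.27, KDM2A at 5.49 and JARID2 at 5.39. The list as fixed thus also held KDM2A, a paralogue of KDM2B that is not itself a Polycomb subunit. This list did not pass against genes with H3K4me3 (odds ratio 2.72, 0.938 to 7.91; exact test, adjusted p = 0.302).

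Developmental transcription factors, classic Polycomb targets, showed the reverse arrangement. H2AK119ub was at 110 of 133 (82.7%; odds ratio 5.87, 3.74 to 9.21; Fisher's exact test, adjusted p = 6.71e-18) and H3K27me3 at 78 (58.6%; odds ratio 3.90; exact test, adjusted p = 1.49e-13), while KDM2B was at 27 (20.3%; odds ratio 0.289; exact test, adjusted p = 3.53e-09). H3K27me3 had a fold of 7.41 at ALX4, 6.16 at PAX5, 6.01 at PAX7 and 5.96 at HOXC4. H2AK119ub had 5.22 at LHX4, 4.63 at GATA5, 4.57 at EMX1 and 4.49 at SOX2. LHX4 also had the highest KDM2B fold of this list, 7.24, followed by MEIS1 at 7.22, IRX5 at 6.10 and IRX3 at 5.93. Haematopoietic genes, used as silent controls, had H2AK119ub at 27 of 33 (81.8%) and H3K27me3 at 24 (72.7%), with folds for H3K27me3 of 5.56 at IKZF3 and 5.53 at ITGAM. KDM2B was at 5 of them (15.2%; odds ratio 0.204; exact test, adjusted p = 0.000848), namely CD14, CD8A, IKZF3, BTK and CD68. H3K4me3 was at 16 of the 33 (48.5%) and MYC at 13 (39.4%), so not all of this list lacked active marks. Olfactory receptors, a second silent control, had H3K27me3 at 262 of 390 (67.2%; odds ratio 5.80, 4.69 to 7.19; exact test, adjusted p = 9.11e-62). H2AK119ub was at 115 of them (29.5%; odds ratio 0.502; exact test, adjusted p = 1.88e-09), fewer than among other genes. Only 10 receptors had H3K4me3, and 6 of these had H2AK119ub (60% against 42.0% of other genes with H3K4me3; odds ratio 2.07; exact test, adjusted p = 0.663), so the lower share was not seen in those few, while the share of all 390 was at percentile 0 of the random lists matched on H3K4me3. KDM2B was at 3 receptors, OR2M2, OR52K1 and OR4A47, and MYC at 3 others, OR14A2, OR2V2 and OR52N2. Of the 108 tests of 18 lists by 6 targets, 47 passed, 30 of them higher and 17 lower. Among genes with H3K4me3, 12 of 90 passed, 5 higher and 7 lower, and the KDM2B share of developmental factors was no longer among them (odds ratio 0.533; exact test, adjusted p = 0.148). The lower KDM2B shares of haematopoietic genes (5 of 16, odds ratio 0.224; exact test, adjusted p = 0.0403) and olfactory receptors (1 of 10, odds ratio 0.0549; exact test, adjusted p = 0.00300) still passed. Placed among random lists with as many H3K4me3 genes, the share of all developmental factors with KDM2B was at percentile 0.89. The KDM2B share was at percentile 96.2 for the synthetases, 96.5 for the glutamine list, 97.4 for other Polycomb subunits, 87.3 for the ATF4-responsive list and 56.1 for the ribosome list.

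At single gene ends the strongest peaks of the other lists were at genes of other kinds. The MYC fold was 118 at EIF5A, a translation factor gene, 86.8 at the shared end of EEF1B2 and NDUFS1 and 85.1 at that of MGME1 and SNX5. H3K27ac reached 145 at EEF1A1, another translation factor gene, 132 at UQCC1, 123 between ANAPC13 and CEP63 and 122 at ZC3H4. H3K4me3 reached 83.4 between PASK and PPP1R7, 83.3 at GMNC, 81.7 at IQGAP1 and 81.5 at RNASEH1. H2AK119ub reached 7.33 at MUC4, a mucin gene, and LOC124905352, 6.76 at GTF2H2C_2, 6.51 at PDGFA and 6.47 at BEAN1. H3K27me3 reached 8.23 at POTEJ, 8.04 at GOLGA6L22, 8.02 at IGLL5 and TSHZ2 and 8.01 at GAGE12B; POTEJ, GOLGA6L22, GAGE12B and GTF2H2C_2 belong to families of near-identical copies, where read placement is uncertain.

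By chromosome, compared only after the data were seen, KDM2B was at 8.84% of 848 genes on X and 48.3% of genes on chromosomes 1 to 22 (odds ratio 0.104, 0.0817 to 0.132; Fisher's exact p = 3.90e-132, two-sided). MYC was at 44.7% and 65.0% of the same genes, and H3K4me3 at 52.9% and 70.1%. H2AK119ub was at 12.9% of genes on X, 19.1% on chromosome 4, 67.2% on chromosome 19 and 72.9% on chromosome 22.

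**Figure D5:**
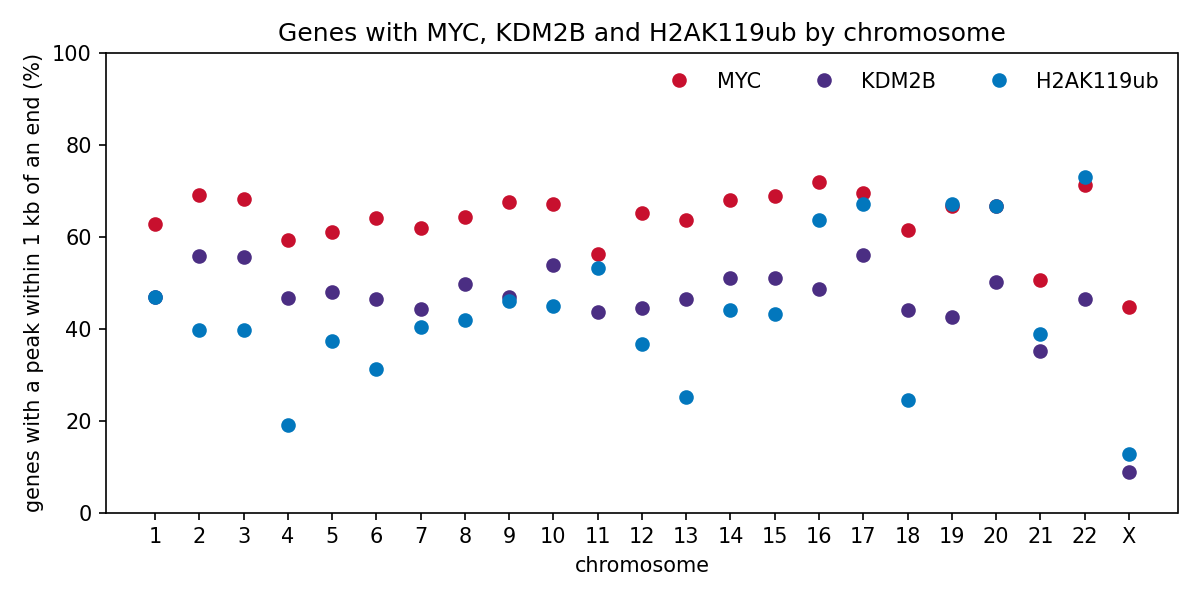
Share of genes (%, vertical axis) with MYC, KDM2B or H2AK119ub within 1 kb of an end (coloured points), by chromosome (horizontal axis). KDM2B was at 8.84% of genes on X and at 35.1% to 55.9% on the other chromosomes, while H2AK119ub ran from 12.9% on X to 72.9% on chromosome 22.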

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

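No test was run in this part. Peaks on sequences other than chromosomes 1 to 22 and X entered no comparison, and every list held some: 36 for KDM2B, 24 for MYC, 43 for H3K4me3, 36 for H3K27ac, 38 for H2AK119ub and 19 for H3K27me3. They drew attention as signal outside the measurements compared. The counts are given without an explanation.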

How the results depend on the processing

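Settings with whole genes, only the gene end with H3K4me3, or strata of H3K4me3 were chosen after the results were seen. Of 135 alternative values over 15 results, 108 kept their direction and their side of the threshold, or for a count stayed within 1.5 times. All alternatives run kept the excess of KDM2B at gene ends (ratio 7.56 to 19.4), the higher odds of H3K4me3, H3K27ac and MYC at genes with KDM2B, the lower odds of H3K27me3 there (0.110 to 0.276), and the pairing of H3K27me3 with H2AK119ub (6.07 to 33.6). The remaining values are odds ratios with unadjusted exact tests, and where they differ the cause was not tested. H2AK119ub at genes with KDM2B among genes with H3K4me3, 0.960 as reported, moved in all 10 alternatives. It was lower and past the threshold with 500 bp windows (0.854), summits (0.870), 1 gene per set of overlapping windows (0.90) and X left out (0.848). It was above 1 with 2500 bp windows (1.15), q under 1e-5 (1.09), the 15000 peaks of highest fold (1.39), whole genes (1.20), strata of H3K4me3 width and fold (1.65) and H3K4me3 peaks as units in such strata (5.00). Over all genes, H2AK119ub lost its difference with 2500 bp windows (0.973) and reversed over whole genes (1.09). H3K27me3 among genes with H3K4me3 reversed in the strata over genes (1.08, 95% interval 0.957 to 1.23) and over peaks (2.75). For the 173 amino acid genes, KDM2B passed the threshold with 500 bp windows (1.40) and 1 gene per set of windows (1.69). MYC passed with 2500 bp windows (1.45), q under 1e-5 (1.41), the 15000 peaks (1.52), 1 gene per set of windows (1.51) and whole genes (1.67). With only the gene end with H3K4me3 the odds ratios were lowest, at 1.19 for KDM2B and 1.01 for MYC, and neither passed. Against genes with H3K4me3 as the background neither factor passed for these genes. Both factors together passed with 500 bp windows (1.38), the 15000 peaks (1.38) and 1 gene per set of windows (1.66), while H2AK119ub turned to 1.02 with 500 bp windows and 1.08 with the 15000 peaks. List tests that passed fell from 47 of 108 to 12 of 90 with genes with H3K4me3 as the background, which tests fewer genes and lists by 1 target fewer, and were 47 with q under 1e-5 and 50 with 2500 bp windows. Not run were another choice of start site, CpG strata and the 4 alternatives of the E-box count, which need strand or sequence, and leaving out each library. No paired analysis was possible because each list is 1 per target and carries no replicate number. Depth is unknown, so a gene without a peak is not shown to lack binding.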

Other observations

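The tests for silent families on X and the settings in strata of H3K4me3 were chosen after their results were seen, and all 3 patterns weighed here were picked after seeing the data. Among lists fixed beforehand, enzymes of the tricarboxylic acid cycle had MYC, H3K4me3 and H3K27ac at all 24 genes and H3K27me3 at 0. KDM2B was at 17 of 24 (70.8%; odds ratio 2.78; Fisher's exact test, adjusted p = 0.0504), with folds of 6.98 at IDH3A, 6.97 at SDHD in a peak shared with NKAPD1 and TIMM8B, 5.19 at SDHA and 4.78 at FH. Cholesterol synthesis enzymes had MYC at 21 of 23 (91.3%; exact test, adjusted p = 0.0193) and KDM2B at 15 (65.2%; exact test, adjusted p = 0.169), with folds of 5.63 at TM7SF2 and 5.43 at MVD and SC5D. Against genes with H3K4me3 the MYC share of this list no longer passed (odds ratio 2.06; exact test, adjusted p = 0.969). Glycolytic genes had KDM2B at 18 of 27 (66.7%; exact test, adjusted p = 0.105), with 7.16 at PKM, 6.11 at PFKP, 5.98 at PFKFB3 and 5.79 at the glucose carrier gene SLC2A1.

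Luminal and epithelial genes, many of them silent in mesenchymal breast cancer lines, had H2AK119ub at 21 of 30 (70.0%; odds ratio 2.84, 1.3 to 6.21; Fisher's exact test, adjusted p = 0.0226), with folds of 4.70 at ELF3, 4.54 at OVOL1, 4.21 at SPDEF and 3.84 at CDH1, the E-cadherin gene. Against genes with H3K4me3, H2AK119ub was at 16 of 23 and no longer passed (odds ratio 3.16; exact test, adjusted p = 0.0644), while the share of all 30 was at percentile 99.8 of random lists with as many H3K4me3 genes. H3K27me3 was at 8 of the 30. Mesenchymal and basal genes had H2AK119ub at 14 of 31 (45.2%; exact test, adjusted p = 1) and H3K27ac at 24, with folds of 120 at FOSL1, 105 at CCN1, 104 at AXL and 81.1 at EGFR. The difference between these 2 lists was not tested. H3K27me3 peaks merged across 3 kb gave 39842 domains, 1024 of them at least 100 kb and the longest 1671 kb. H2AK119ub gave 59477, of which 217 were that long. The longest stretch with genes but no peak of any list was 4920 kb on chromosome 9 (20757231 to 25677008), with 24 genes including MTAP, CDKN2A and CDKN2B. Copy number was not examined here, so the absence of peaks there is not shown to be a state of chromatin.

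Nearly all genes with KDM2B at an end also had MYC. The greater length of the MYC list alone would leave no relation with lists of equal length: with 15000 peaks each, the odds ratio matched on H3K4me3 width and fold was 3.58 (95% interval 3.21 to 4.0), down from 21.1 with the full lists, so the relation was weaker once both lists were shortened by fold. If both factors lay anywhere within the same active regions, their summits would be as far apart as when placed by chance. The median distance was 164 bp against 822 bp when MYC summits were placed as in other H3K4me3 peaks of like width, a ratio of 0.20 over 15362 summits, and no placement gave under 797 bp. A shared short site, such as open or CpG-rich DNA bound by both, may remain as an explanation and was not tested, and the design gives no biological explanation that could be tested.

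H2AK119ub was more frequent at KDM2B sites once H3K4me3 width and fold were matched. Wider H3K4me3 peaks touch more H2AK119ub, so H2AK119ub was also counted only within 500 bp either side of the H3K4me3 summit. KDM2B was still counted anywhere in the H3K4me3 peak. Over 71554 H3K4me3 peaks the matched odds ratio was then 6.77 (95% interval 6.11 to 7.50). With H2AK119ub counted over the whole peak it was 5.00. The same matching over peaks gave 2.75 for H3K27me3, so the excess was not particular to H2AK119ub. Chromosome X, low in both, was not the sole source, since over chromosomes 1 to 22 the matched odds ratio over genes was 1.52 (1.38 to 1.68). As a hypothesis, KDM2B may go with H2AK119ub at genes with the same H3K4me3, each counted at either end of the gene. No matched value was computed for a single gene end. Without matching, the odds ratio among genes with H3K4me3 ran from 0.748, at the end with H3K4me3 alone, to 1.39 by setting. CpG content and the depth of each list remain open, and no biological explanation was tested.

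KDM2B was at the ends of fewer genes on chromosome X than on chromosomes 1 to 22. Silent gene families on X were not the whole cause: among genes with H3K4me3, H3K27ac and MYC, 17.9% of 369 on X had KDM2B and 76.4% of 11621 elsewhere (odds ratio 0.0671, 0.0512 to 0.0879). Fewer reads over X would lower the −log10 q of other peaks too, and matching genes with H3K4me3 on the −log10 q of MYC and H3K4me3 moved the odds ratio from 0.0904 to 0.282 (0.214 to 0.372). The interval stayed below 1, but −log10 q also rises with the strength of a peak, so this matching cannot tell fewer reads from weaker peaks. Peaks with a fold of 3 to 4 were compared by chromosome for their median −log10 q. On X it equalled that on chromosomes 4 and 18 for MYC (6.89), H3K4me3 (8.73) and H3K27ac (10.1). KDM2B was at 46.6% and 44.1% of genes on those chromosomes. The H3K4me3 value also recurred on chromosomes 13, 21 and 22, and the H3K27ac value on 6 and 13. A median that repeats across chromosomes cannot rank their reads, so no conclusion was drawn from it. Median folds of all peaks were higher on X than on any other chromosome for MYC (4.94), H3K4me3 (5.42) and H3K27ac (4.17). The KDM2B median itself was lowest on X, at 4.55. A KDM2B list with less depth than the others could be lowered more by the same loss of reads and stays open, and no biological explanation was tested.

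Some KDM2B peaks had a q under 1e-100 with a fold under 3. There were 95, none within 1 kb of a gene end, and 59 lay in 5 bins of 1 Mb, 27 of them on chromosome 1 between 143184841 and 143267105. Peaks of a like kind (q under 1e-50, fold under 3) in another list overlapped 73 of them (76.8%), 69 in the MYC list, 42 in the H2AK119ub list, 1 each in the H3K4me3 and H3K27me3 lists and 0 in the H3K27ac list. This overlap was a test set beforehand: at least 50% was expected if such peaks came from sequence with raised read depth in every library, and under 10% if not. The share met the first of these, but mainly through the MYC and H2AK119ub lists. The H3K4me3, H3K27ac and H3K27me3 lists overlapped 1, 0 and 1 of the 95, so raised depth in every library was not shown. Peaks of that kind numbered 107 in the MYC list and 105 in the H2AK119ub list. There were 6 for H3K4me3, 20 for H3K27ac and 10 for H3K27me3, so these lists had few to share. Whether low numbers alone account for the lack of overlap was not tested. Of the 5 bins, the others lay near 26.6 Mb on chromosome 17, 125.2 Mb on chromosome 1, 49.5 Mb on chromosome 5 and 46.4 Mb on chromosome 16. No regions were excluded here beforehand, and the kind of sequence in these bins was not examined, so an artifact of sequence stays open. The peaks were not weighed further.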
